A study of Mus musculus with 6 samples.

How the data were processed

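RNA was taken from wild-type mouse primary articular chondrocytes, per the labels, and messenger RNA was captured with oligo(dT) beads, fragmented, copied into cDNA and sequenced from DNA nanoballs. All 6 libraries had values in the deposited table. They formed 3 groups of 2 by their condition labels: control, aging SNL, and aging SNL with spesolimab. The abbreviations SNL and CCs in the labels were not expanded there and are used as given. Strandedness and the gene annotation were not given in the sources used here, so reads of overlapping genes, antisense genes and near-identical family members such as Serpina3m, Serpina3n and Serpina3c, or Saa1 and Saa2, may be divided unevenly between them.

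The authors' table gave a gene identifier, a symbol and 3 kinds of value per library. The expected counts were deposited unscaled, per the file headers and their values, of which 12.3% were not whole numbers. The TPM values were scaled by the authors to the same total in each library, per the file headers. The FPKM values were likewise deposited per the file headers. They were used here only to derive effective transcript lengths from the counts. Bowtie2 2.3.4.3, RSEM 1.3.1, DESeq2 1.4.5 and the mouse build GRCm39 are named in the submitters' processing notes, without saying which step used which. The authors' 9 columns of group averages were not used. The table listed 22173 genes, of which 17189 had values and 4984 had empty cells in every library. No genome was used here, and positions of genes are therefore not given.

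The expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 13399 genes. Library sizes were scaled by TMM, and CPM values below are the usual depth-scaled counts, with TMM-scaled library sizes as the depth. The quasi-likelihood test was fitted to all 6 libraries with 1 mean per group and 3 residual degrees of freedom, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors of log2 fold changes of single genes are approximate standard errors from the fit named with them. They were derived as the size of the log2 fold change divided by the square root of its quasi-likelihood F statistic. Errors given with the mean or median of a list are standard errors of the mean across its genes. They treat genes as independent and do not measure the spread between libraries. This fit, the gene lists, the alternatives and the rule for naming genes were set before the data were examined.

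Totals ranged from 16566791 to 17312833 counts per library. At 5 CPM the counting error at the lowest of these depths was 11%, so that the spread between libraries, not depth, limited most tests. The biological coefficient of variation was 0.205 over 6 libraries and 0.0925 both without aging SNL replicate 1 and without replicate 2. A single aging SNL library adds nothing to the estimated spread, so these values do not tell the 2 replicates apart. The counts of the 2 libraries of a group differed by more than counting noise in each group. The chi-square per degree of freedom was 12.95 in control, 226.7 in aging SNL and 16.89 in the spesolimab group. None was therefore treated as the same library sequenced again. Separate preparations of the same RNA can exceed counting noise too, so this cannot show that the replicates are separate cultures.

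Gene lists were tested with camera of limma 3.58.1 on log2 CPM values with a prior count of 2 and a preset correlation of 0.01, adjusted over the 30 lists that had at least 5 tested genes. Of 33 lists, 15 covered the question of the study and 18 covered metabolism, stress and other cell types; the lists of mitochondrially encoded and of globin genes had 0 tested genes, and the list of neutrophil and lymphocyte markers had 1, Camp. Each camera result was set beside camera with an estimated correlation and beside fry. Fry was read for a shared direction of the members of a list unless stated otherwise. Older symbols used in the table were matched after the table was seen: Il1f6, Il1f8, Il1f9 and Il1f5 for the IL-36 ligands and their receptor antagonist, and Hc for complement C5.

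Genes were named by a rule. For each of the first 2 comparisons it took up to 8 genes with the largest rise and 8 with the largest fall among those past the threshold, with a mean of at least 5 CPM and no overlap between groups, leaving out provisional gene names. It also took the 2 members with the lowest p of each list on the question, and always Il1rl2, Il1rap, the IL-36 ligands and antagonist, Sox9, Acan, Col2a1 and Mmp13. The third comparison took 4 and 4. Because 0 genes passed in the fit of 6 libraries, the part of the rule that needs a threshold was applied to fits without aging SNL replicate 1, without aging SNL replicate 2, and, for spesolimab against control, of the 4 libraries compared. Those fits were chosen after the data were seen. Where 1 aging SNL library is left out, the other is assumed to vary like the libraries of the other groups, which is doubtful, because the aging SNL replicates differed most. Members of other lists, and the genes Fkbp5 and Gm44504, were named after their values were seen.

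The scripts were tested on simulated counts with the means and library sizes of these data and 200 changed genes in each of 3 draws. All simulated groups had the same spread for a gene. In the data the log2 differences between replicates had an SD of 0.335 in control, 0.789 in aging SNL and 0.361 with spesolimab. Recovery and false calls in fits with aging SNL libraries may therefore differ from those simulated. For aging SNL against control with 6 libraries, over 13399 genes, edgeR recovered 0.995% of the changes of 1.5-fold, 15.9% of those of 2-fold and 78.8% of those of 4-fold, with 6 false calls per draw. DESeq2 recovered 11.9%, 59.2% and 87.4% with 55.3 false calls per draw. Without aging SNL replicate 1, over 13630 genes, edgeR recovered 31.3%, 73.1% and 89.9% with 25.3 false calls per draw. For spesolimab against control with 4 libraries, over 13283 genes, it recovered 55.7%, 81.1% and 95.5% with 26.3 false calls per draw. A simulated list of 28 genes shifted by 0.5 on the log2 scale was called by camera with the preset correlation in 3 of 3 draws, by fry in 2 and with an estimated correlation in 0, in the 6 libraries. Other lists, not shifted as a whole, were called 2 times in these draws with the preset correlation, 1 time by fry and 0 times with an estimated correlation. Genes were drawn independently there, while the correlations estimated in the data ranged from -0.0857 to 0.857 over the lists. The draws therefore cannot show how often the preset correlation calls lists of correlated genes falsely.

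Alternatives were DESeq2 1.42.0, scaling by DESeq2 size factors or by the upper quartile, no filter or a filter of 10 CPM in 2 libraries, limma on log2(TPM + 1) and log2(TPM + 0.1) of genes above 1 TPM in at least 2 libraries, a 2-fold minimum, only the groups compared, the replicate number as a block, and each library left out in turn. Comparisons that share libraries were set beside 30 simulations of unchanged libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.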

Results

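Gene expression was measured by RNA-seq in primary articular chondrocytes of wild-type mice, the cells that make and maintain joint cartilage. Per its title, the series concerns aged skin, experimental osteoarthritis and signalling through the IL-36 receptor. The 6 libraries were 2 of control cells, 2 of cells under a condition labelled aging SNL, and 2 of cells under that condition with spesolimab, a humanised antibody made to block the IL-36 receptor. The labels did not say whether the replicates came from separate animals or cultures, so p-values of single genes measure only the spread between these libraries, which may be technical. Those of camera with the preset correlation instead set a list against the other genes under an assumed correlation. They can be very small with 2 libraries per group. The libraries held 17312833 and 17064957 counts in control, 16693914 and 16566791 in aging SNL, and 17241498 and 17272812 with spesolimab.

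Aging SNL replicate 1 stood apart from the other 5 libraries. It had a score of 67.94 on the first principal component, which held 53.8% of the variance, while the others lay between -18.78 and -6.457. Between the aging SNL replicates 1857 genes, 13.9% of those tested, were over 2-fold apart, against 283 between the controls and 349 between the spesolimab libraries. Col2a1, the main collagen of cartilage, took 0.741% of the counts in aging SNL replicate 1 and between 4.37% and 4.79% in the others. Saa3, Lcn2 and Mmp3, which are induced by inflammatory cytokines, together took 5.15% there and between 0.221% and 0.944% elsewhere. Values of each library are therefore given below for many of the genes named.

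Aging SNL cells were compared with control cells to ask what the condition changed in chondrocytes. Genes of the cell cycle and DNA replication fell as a group, with 29 of 30 measured members lower (camera, preset correlation between genes), a call lost with an estimated correlation (adjusted p = 0.548). Mki67, a marker of dividing cells, stood at 84.2 and 114 CPM in control and at 34 and 34 CPM in aging SNL, a log2 fold change of -1.54 ± 0.16 (SE). Serpina3n, an inhibitor of serine proteases, stood at 619 and 591 CPM in control and at 4250 and 4680 CPM in aging SNL, 2.88 ± 0.19 higher on the log2 scale. Neither Mki67 nor Serpina3n was called over all genes in the 6 libraries (edgeR adjusted p = 0.108 and 0.055). Glycolysis and hypoxia genes and cholesterol biosynthesis genes rose as groups, and Wnt pathway genes fell, with both aging SNL libraries on the same side of control in each of these lists. With an estimated correlation these calls were lost too (adjusted p = 0.548, 0.743 and 0.548). Fry called none of these lists (adjusted p = 0.222, 0.276 and 0.195), nor the cell cycle list (fry adjusted p = 0.148). Of all 30 lists fry called only that of TGF-beta and BMP genes.

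The fall of the cell cycle list had an adjusted p = 4.04e-21 in camera with the preset correlation. Of its 30 members 26 were lower when adjusted over the list alone and 0 over all genes tested. Without aging SNL replicate 1, edgeR called 17 of them lower over all genes. Kif20a, a mitotic kinesin, stood at 31.8 and 39.1 CPM in control and at 14.8 and 13 CPM in aging SNL. Bub1, a kinase of the spindle checkpoint, fell by 2.49 ± 0.33 without aging SNL replicate 1 (edgeR adjusted p = 0.0196). In the same fit Pclaf, a partner of the replication clamp PCNA, fell by 2.66 ± 0.21 (adjusted p = 0.00682), and Pole, a catalytic subunit of DNA polymerase epsilon, fell by 2.15 ± 0.32 (adjusted p = 0.0245). Lmnb1, a nuclear lamina gene of the senescence list, was at 15.1 and 14.8 CPM in control and at 4.47 and 6.33 CPM in aging SNL. It was the 1 member of the 20 of that list that passed when adjusted over the list alone. Igfbp7, the other gene named from it, was at 289 and 238 CPM against 484 and 383 CPM.

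Of 22 glycolysis and hypoxia genes 20 were higher, and 4 passed when adjusted over the list alone (camera adjusted p = 1.65e-06; adjusted p = 0.548 with an estimated correlation). Slc2a1, a glucose transporter, was at 137 and 150 CPM in control and at 261 and 239 CPM in aging SNL. Hk2, a hexokinase, was at 42.7 and 49.2 CPM against 67.9 and 72.8 CPM. Bnip3, a hypoxia-induced mitophagy gene, was at 233 and 265 CPM against 342 and 384 CPM. The mean of the list stood 0.45 above the control mean on the log2 scale in each aging SNL library. Of 20 cholesterol biosynthesis genes 19 were higher (camera adjusted p = 6.67e-07; adjusted p = 0.743 with an estimated correlation). Msmo1, a sterol oxidase, passed when adjusted over the list alone, at 56.7 and 53.4 CPM against 103 and 88.5 CPM. Of 20 Wnt pathway genes 15 were lower (camera adjusted p = 0.00145; adjusted p = 0.548 with an estimated correlation), and Wnt7b and Wif1 passed when adjusted over the list alone. Wif1, a secreted Wnt inhibitor, was at 17.4 and 15.7 CPM against 7.14 and 9.34 CPM. TGF-beta and BMP pathway genes fell with 15 of 22 members lower (camera adjusted p = 0.0233; adjusted p = 0.548 with an estimated correlation; fry adjusted p = 0.00776; camera adjusted p = 0.14 without aging SNL replicate 2). Smad6, an inhibitor of BMP signalling, was at 37.1 and 33.9 CPM against 13.7 and 17.4 CPM, and Id3, a BMP target, at 121 and 110 CPM against 70.4 and 68.9 CPM.

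NF-kB feedback and target genes rose as a group with 20 of 22 members higher and 0 past the threshold when adjusted over the list alone (camera adjusted p = 0.00147; adjusted p = 0.782 with an estimated correlation). The list mean was 1.52 above control in aging SNL replicate 1 and 0.15 above it in replicate 2, and without replicate 1 the call was lost (camera adjusted p = 0.919). Saa3, an acute-phase protein, was at 845 and 545 CPM in control and at 15000 and 3230 CPM in aging SNL. Lcn2, an iron-scavenging protein, was at 1230 and 995 CPM against 16700 and 3820 CPM. Both rose in the fit without replicate 1 too, by 2.22 ± 0.23 (edgeR adjusted p = 0.0115) and by 1.78 ± 0.17 (adjusted p = 0.0107). Nos2, the inducible nitric oxide synthase, was at 3.77 and 5.49 CPM in control, 266 CPM in aging SNL replicate 1 and 10.8 CPM in replicate 2. Oxidative stress and ferroptosis genes also rose, with 17 of 20 members higher and 2 past the threshold when adjusted over the list alone (camera adjusted p = 0.00108; adjusted p = 0.782 with an estimated correlation; camera adjusted p = 0.216 without replicate 1). Their mean was 1.19 above control in replicate 1 and 0.30 above it in replicate 2. Fry called neither list (adjusted p = 0.622 for NF-kB targets and 0.557 for oxidative stress). Nqo1, a quinone reductase, was at 20.3 and 23.9 CPM against 97.1 and 55.5 CPM. Gpx3, a secreted glutathione peroxidase, was at 349 and 201 CPM against 1140 and 854 CPM.

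The 2 aging SNL libraries lay on opposite sides of control in the lists of inflammatory cytokines and chemokines and of cartilage matrix. The cytokine list had a mean of 1.89 above control in replicate 1 and of -0.62 in replicate 2. It was not called in the 6 libraries (camera adjusted p = 0.383), was higher without replicate 2 (adjusted p = 8.76e-07) and lower without replicate 1 (adjusted p = 0.000197), both lost with an estimated correlation (adjusted p = 0.631 and 0.594). Csf1, the macrophage growth factor, was lower in both replicates, at 688 and 617 CPM in control and at 387 and 240 CPM in aging SNL. Ccl5, a chemokine, was at 0.343 and 0.505 CPM in control, 18.4 CPM in replicate 1 and 0.964 CPM in replicate 2. The cartilage matrix list had a mean of -1.31 in replicate 1 and of 0.57 in replicate 2 and was not called in the 6 libraries (camera adjusted p = 0.383). It was lower without replicate 2 (adjusted p = 9.08e-06) and higher without replicate 1 (adjusted p = 7.62e-05), again lost with an estimated correlation (adjusted p = 0.631 and 0.594). Col2a1 was at 45300 and 41800 CPM in control, 7680 CPM in replicate 1 and 45400 CPM in replicate 2. Acan, the core protein of the main cartilage proteoglycan, was at 2500 and 3740 CPM in control, 637 CPM in replicate 1 and 7530 CPM in replicate 2. Cilp, a protein of the cartilage intermediate layer, was at 5.2 and 2.86 CPM in control against 7.45 and 25.1 CPM. Prg4, the joint lubricant lubricin, was at 162 and 144 CPM against 488 and 184 CPM. Sox9, the master regulator of chondrocyte identity, was at 149 and 156 CPM in control, 71.5 CPM in replicate 1 and 207 CPM in replicate 2. Mmp13, the main collagenase of cartilage, was at 2110 and 2530 CPM in control, 7020 CPM in replicate 1 and 2920 CPM in replicate 2.

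Il1rl2, which encodes the IL-36 receptor, the target of spesolimab, was detected in each library, at 16.3 and 11.2 CPM in control, 57.2 and 15.9 CPM in aging SNL and 19.2 and 14.6 CPM with spesolimab. Its log2 fold change in aging SNL was 1.41 ± 0.60 in the 6 libraries (edgeR adjusted p = 0.419) and 0.21 ± 0.25 without aging SNL replicate 1 (adjusted p = 0.685). Il1rap, its co-receptor, was at 32.7 and 30.9 CPM in control and at 60.7 and 26.4 CPM in aging SNL. Of the IL-36 ligands, Il1f9, the gene of IL-36 gamma, had 2 and 2 counts in control, 15 and 1 in aging SNL and 2 and 3 with spesolimab, too few to be tested in the 6 libraries. In the fit without aging SNL replicate 2, which rests on the 15 counts of replicate 1, it was 2.96 ± 0.74 higher in aging SNL (edgeR adjusted p = 0.0291) and differed by -2.61 ± 0.71 with spesolimab (adjusted p = 0.0457). Il1f6, Il1f8 and the antagonist gene Il1f5 had empty cells and were not analysed here. The list of IL-36 and IL-1 family genes, with 11 of 19 members measured, was not called (camera adjusted p = 0.284), with Il18r1 at 0.114 and 0 CPM in control against 0.311 and 1.75 CPM and Il1r2 at 0.0572 and 0.449 CPM against 2.17 and 0.783 CPM. The list of IL-1 receptor adaptors and kinases was not called either (camera adjusted p = 0.075), with Chuk, an NF-kB pathway kinase, at 53.4 and 58.3 CPM against 68.4 and 64.8 CPM and Rela, an NF-kB subunit, at 50.4 and 50 CPM against 59.8 and 55.7 CPM.

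Several lists were not called by camera but held members past the threshold when adjusted over the list alone. Of 22 matrix-degrading proteases these were Plau, the urokinase plasminogen activator, at 48.1 and 46.6 CPM in control and 20.2 and 17.9 CPM in aging SNL, and Adamts9, at 118 and 122 CPM against 35.2 and 39 CPM (list: camera adjusted p = 0.475). Of 15 protease inhibitors 3 were higher and 2 lower, among them Serpina3n and Cst3, which encodes cystatin C, at 445 and 351 CPM against 928 and 907 CPM (list: camera adjusted p = 0.292). Of 15 genes of chondrocyte hypertrophy and mineralization 2 were higher and 3 lower, with Enpp1, a source of pyrophosphate, at 119 and 107 CPM against 221 and 165 CPM and Vegfa, an angiogenic factor, at 200 and 223 CPM against 379 and 287 CPM (list: camera adjusted p = 0.357). Foxo3 was the 1 of 18 chondrocyte transcription factors to pass, at 86 and 84.7 CPM against 150 and 147 CPM, and Erg, the other named member, was at 13.5 and 15 CPM against 20.5 and 20.6 CPM (list: camera adjusted p = 0.383). Tagln, a smooth muscle actin-binding protein, was the 1 of 22 dedifferentiation and fibrous matrix genes to pass, at 60.2 and 48.6 CPM against 16.8 and 16 CPM, with the actin gene Acta2 at 128 and 108 CPM against 20.7 and 50 CPM (list: camera adjusted p = 0.335). C3 and C4b, which encode complement components, passed of 16 complement genes, C3 at 451 and 295 CPM against 2030 and 884 CPM and C4b at 887 and 709 CPM against 1880 and 1380 CPM (list: camera adjusted p = 0.31). Macrophage markers, on average 0.90 and -0.90 from the control mean in the controls, stood at 0.75 and -0.42 in the aging SNL libraries, and the complement list moved with them, at 0.35 and -0.35 against 0.49 and -0.02. Of 21 interferon-stimulated genes 0 passed, with Stat2 at 34.4 and 29.7 CPM against 46.9 and 45.8 CPM and Gbp2 at 15.8 and 16.5 CPM against 27.2 and 16.4 CPM (list: camera adjusted p = 0.569). Read for changes in either direction, fry called protease inhibitors (adjusted p = 0.00048), dedifferentiation genes (0.0233) and chondrocyte transcription factors (0.0251). It did not call proteases (0.125), hypertrophy and mineralization (0.484), complement (0.213) or interferon-stimulated genes (0.73).

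Further lists not called in this comparison were the senescence list (camera adjusted p = 0.681), nuclear-encoded oxidative phosphorylation (0.383), the unfolded protein response (0.681), heat shock (0.383), immediate early genes (0.131) and cytosolic ribosomal proteins (0.125). Of markers of other cells, those of synovial fibroblasts gave a camera adjusted p = 0.075, macrophages 0.507, endothelial and mural cells 0.383, keratinocytes 0.564, osteoblasts and osteoclasts 0.475, and adipocytes and muscle 0.559. Leaving out 1 library gave a call to several lists not called in 6. Without aging SNL replicate 1 camera called synovial fibroblast markers (adjusted p = 0.0186) and chondrocyte transcription factors (0.00858) higher, as it did cartilage matrix, and ribosomal proteins (0.000919) and dedifferentiation genes (0.0313) lower. Without aging SNL replicate 2 it called adaptors and kinases (0.0192), proteases (0.0156), protease inhibitors (0.0348) and immediate early genes (0.018) higher and interferon-stimulated genes (0.0406) lower. With an estimated correlation 0 lists were called in these 2 fits (lowest adjusted p = 0.594 and 0.631). Without control replicate 1 camera called complement (0.0147) and markers of macrophages (0.00109), adipocytes and muscle (0.0177) and synovial fibroblasts (0.0147) higher. An estimated correlation was not run in that fit. In the 6 libraries camera with it gave these lists an adjusted p of 0.548 to 0.839.

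Across all genes, edgeR called 0 of 13399 genes in aging SNL against control, with a lowest adjusted p of 0.055, for Serpina3n, Pclaf and others. At an unadjusted p under 0.05 there were 1694 genes where 670 are expected by chance. DESeq2 called 445 genes, 227 higher and 218 lower, and limma on TPM called 0. In simulated data with equal spread in all groups DESeq2 made 55.3 false calls per draw. With aging SNL replicate 1 left out, edgeR called 467 genes, 247 higher and 220 lower, and of these DESeq2 shared 232. With replicate 2 left out, it called 3525 genes, 1834 higher and 1691 lower. Without replicate 1 the largest rises were in Serpina3m, at 11.1 and 9.48 CPM in control and 471 and 151 CPM in aging SNL, Saa1, Aox3, Serpina3n, Magel2, Serpina3c, Cilp and Cdhr4, by 2.62 to 3.88 on the log2 scale. The largest falls were in Galnt14, a transferase of O-linked glycosylation, at 23 and 19.8 CPM against 2.36 and 2.89 CPM, Dio3, which inactivates thyroid hormone, at 26.8 and 27.6 CPM against 5.84 and 4.22 CPM, Pclaf, Bub1, Angpt4, Pole, Lurap1l and Gask1b. Replicate 1 lay on the same side of both controls in all of these rises and falls except Aox3, Magel2 and Gask1b. Aox3 was at 3.66 and 2.52 CPM in control against 3.54 and 31.9 CPM. Magel2 was at 1.77 and 3.03 CPM against 0.311 and 18.3 CPM, and Gask1b at 12.9 and 9.87 CPM against 16.8 and 2.65 CPM. Without replicate 2 the largest rises were in Saa1, Lvrn, Nos2, Serpina3m, Ccl5, Vnn3, Saa2 and Mmp3, a stromelysin at 854 and 579 CPM in control, 21800 CPM in replicate 1 and 2370 CPM in replicate 2. The largest falls were in Slc16a14, Ngfr, Ostn, Trim66, Sh3tc2, Matn3, Cyb5r2 and Lctl. Of these 8, Ostn was at 9.37 and 16.1 CPM in control and at 0.373 and 16.3 CPM in aging SNL, and the cartilage matrix gene Matn3 at 37.4 and 46.5 CPM against 2.42 and 132 CPM.

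**Figure D1:**
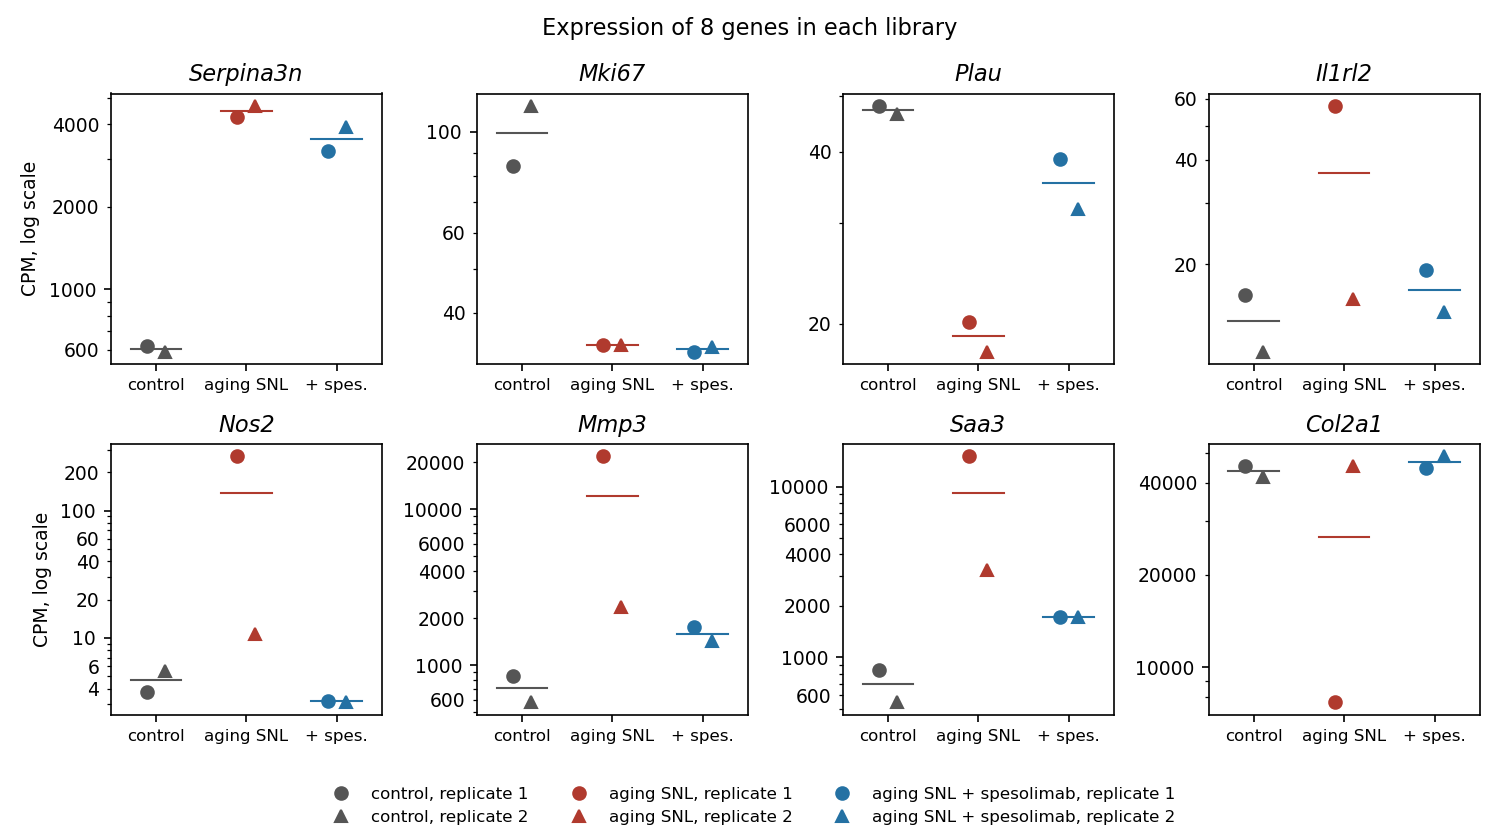
Expression of 8 genes in each of the 6 libraries, in CPM on a log axis; points are libraries and bars are group means. Serpina3n and Mki67 differ between control and aging SNL by more than the replicates differ, while Nos2, Mmp3, Saa3, Il1rl2 and Col2a1 are far apart between the 2 aging SNL libraries.

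Cells with spesolimab were compared with aging SNL cells to ask what the antibody changed under that condition; whether it blocked the mouse receptor in these cells was not measured. NF-kB feedback and target genes fell as a group, with 21 of 22 members lower, glycolysis and hypoxia genes fell with 21 of 22 lower, and Wnt pathway genes rose with 15 of 20 higher. These 3 calls were lost with an estimated correlation (adjusted p = 0.723, 0.667 and 0.667). Fry called none of these lists (adjusted p = 0.768, 0.389 and 0.389). Of all 30 lists it called only that of TGF-beta and BMP genes. Plau, lower in aging SNL than in control, stood at 20.2 and 17.9 CPM in aging SNL and at 38.8 and 31.8 CPM with spesolimab, 0.89 ± 0.13 higher on the log2 scale. It was not called by edgeR over all genes, where the lowest adjusted p was 0.956. The antibody group did not differ in this way in the cell cycle list, where Mki67 was at 34 and 34 CPM in aging SNL and at 32.9 and 33.7 CPM with spesolimab (list: camera adjusted p = 0.74).

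The NF-kB list had a camera adjusted p = 2.23e-08, an adjusted p = 0.723 with an estimated correlation, and a camera adjusted p = 0.00499 without aging SNL replicate 1. Its mean from control was 1.52 and 0.15 in aging SNL and -0.04 and -0.10 with spesolimab. Nos2 was at 266 and 10.8 CPM in aging SNL and at 3.21 and 3.12 CPM with spesolimab. Tnfaip3, a feedback inhibitor of NF-kB, was at 16.4 and 8.07 CPM against 5.55 and 5.12 CPM. IL-1 receptor adaptors and kinases fell, with 12 of 17 lower (camera adjusted p = 0.0375; adjusted p = 0.723 with an estimated correlation; camera adjusted p = 0.722 without aging SNL replicate 1 and 0.13 without spesolimab replicate 2). Chuk was at 68.4 and 64.8 CPM in aging SNL and at 55.3 and 56.3 CPM with spesolimab, and Irak1, a receptor-proximal kinase, at 78.9 and 67 CPM against 62.8 and 60.6 CPM. Inflammatory cytokines and chemokines fell, with 13 of 16 lower (camera adjusted p = 0.00748; adjusted p = 0.723 with an estimated correlation). Cxcl1, a neutrophil chemokine, was at 598 and 41.8 CPM in aging SNL and at 29.2 and 33.3 CPM with spesolimab, and Cxcl2 at 46 and 1.2 CPM against 0.818 and 1.06 CPM. Without aging SNL replicate 1 the direction of the cytokine list turned and it was not called (camera adjusted p = 0.352), and without spesolimab replicate 2 the call was lost too (adjusted p = 0.071).

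Glycolysis and hypoxia genes had a camera adjusted p = 1.72e-07, and adjusted p = 0.667 with an estimated correlation. Slc2a1 was at 261 and 239 CPM in aging SNL and at 158 and 196 CPM with spesolimab, and Hk2 at 67.9 and 72.8 CPM against 52.2 and 53.4 CPM. The Wnt list had a camera adjusted p = 0.000804, an adjusted p = 0.667 with an estimated correlation and a camera adjusted p = 0.084 without aging SNL replicate 2, with Wnt7b at 0.248 and 0.12 CPM in aging SNL and at 1.17 and 0.942 CPM with spesolimab. Cholesterol biosynthesis genes fell, with 17 of 20 lower (camera adjusted p = 0.000858; adjusted p = 0.723 with an estimated correlation; camera adjusted p = 0.221 without aging SNL replicate 2 and 0.875 without spesolimab replicate 1), and Msmo1 was at 103 and 88.5 CPM against 71.4 and 81.6 CPM. TGF-beta and BMP pathway genes rose, with 13 of 22 higher (camera adjusted p = 0.0303; adjusted p = 0.667 with an estimated correlation; fry adjusted p = 0.0257; camera adjusted p = 0.314 without aging SNL replicate 2 and 0.103 without spesolimab replicate 2). Smad6, Id3 and Tgfb3 passed when adjusted over that list alone, with Tgfb3 at 60.3 and 83.6 CPM in aging SNL and at 141 and 122 CPM with spesolimab. Oxidative stress and ferroptosis genes fell, with 19 of 20 lower (camera adjusted p = 2e-05; adjusted p = 0.723 with an estimated correlation; camera adjusted p = 0.0961 without aging SNL replicate 1). Nqo1 was at 97.1 and 55.5 CPM against 26.7 and 41.8 CPM, and the cystine transporter gene Slc7a11 at 55.8 and 25.9 CPM against 18 and 18.1 CPM. Cytosolic ribosomal protein genes rose, with 20 of 24 higher by a median of 0.08 on the log2 scale (camera adjusted p = 0.0147; adjusted p = 0.723 with an estimated correlation; camera adjusted p = 0.848 without aging SNL replicate 2 and 0.145 without spesolimab replicate 1).

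Cartilage matrix genes rose against aging SNL, with 19 of 24 higher (camera adjusted p = 0.00114; adjusted p = 0.723 with an estimated correlation), but the direction turned without aging SNL replicate 1 (camera adjusted p = 0.052). Comp, a cartilage matrix glycoprotein, was at 1340 and 3270 CPM in aging SNL and at 3800 and 3120 CPM with spesolimab, and Cilp2 at 1.24 and 1.81 CPM against 3.04 and 2.18 CPM. With spesolimab, Col2a1 was at 44500 and 48700 CPM, Acan at 3310 and 6490 CPM, Sox9 at 164 and 199 CPM, Mmp13 at 2740 and 2860 CPM and Il1rap at 35.4 and 27.4 CPM, each closer to control than to aging SNL replicate 1. Aging SNL replicate 2 was closer to the spesolimab libraries than replicate 1 was, with Col2a1 at 45400 CPM, Acan at 7530 CPM, Sox9 at 207 CPM, Mmp13 at 2920 CPM and Il1rap at 26.4 CPM. Il1rl2 differed by -1.11 ± 0.60 from aging SNL (edgeR adjusted p = 0.956) and by 0.09 ± 0.25 without aging SNL replicate 1 (adjusted p = 0.955), and Il18bp, which binds IL-18, was at 4.66 and 5.3 CPM in aging SNL and at 3.1 and 3.82 CPM with spesolimab (list: camera adjusted p = 0.713).

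Of the proteases, Plau was the 1 of 22 that passed when adjusted over the list alone, and Adamts9 was at 35.2 and 39 CPM in aging SNL and at 69.7 and 49.5 CPM with spesolimab (list: camera adjusted p = 0.991). In each of the lists of protease inhibitors (camera adjusted p = 0.941), hypertrophy and mineralization (0.14), senescence (0.259), interferon-stimulated genes (0.352), dedifferentiation (0.259), complement (0.96) and chondrocyte transcription factors (0.482), 0 members passed when adjusted over the list alone. Timp3, an inhibitor of metalloproteinases, was at 1900 and 3240 CPM in aging SNL and at 5800 and 4440 CPM with spesolimab. Reck was at 140 and 133 CPM against 197 and 157 CPM. Vegfa was at 379 and 287 CPM against 235 and 231 CPM. Ibsp, a bone sialoprotein, was at 78.9 and 73.7 CPM against 329 and 105 CPM. Ereg, an EGF family ligand, was at 78.3 and 18.7 CPM against 12.7 and 14.7 CPM. Mdm2, a p53 target, was at 101 and 88.2 CPM against 76.6 and 79.6 CPM. Mcm3, of the replicative helicase, was at 6.4 and 8.92 CPM against 13.6 and 10.5 CPM, and Ccnb1, a mitotic cyclin, at 12.5 and 9.46 CPM against 8.06 and 7.53 CPM. Gbp2 was at 27.2 and 16.4 CPM against 12.7 and 12.4 CPM, and Ifit2 at 18.7 and 28.4 CPM against 29.1 and 33.4 CPM. Ccn2, a matricellular growth factor, was at 1100 and 1310 CPM against 2610 and 1810 CPM, and the collagen gene Col12a1 at 2300 and 2060 CPM against 3010 and 2870 CPM. C5ar1, a complement receptor of myeloid cells, was at 0.186 and 0.241 CPM against 1.05 and 0.53 CPM, and C3 at 2030 and 884 CPM against 792 and 681 CPM, beside macrophage markers on average 1.16 and -0.31 from the control mean in the spesolimab libraries. Nfatc1 was at 40.4 and 40.7 CPM against 33.6 and 34.4 CPM, and Gli3 at 56.6 and 69.6 CPM against 75.8 and 74.9 CPM.

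Of the remaining lists in this comparison, camera gave adjusted p values of 0.106 for oxidative phosphorylation, 0.74 for the unfolded protein response, 0.156 for heat shock and 0.258 for immediate early genes. For markers of other cells they were 0.506 for macrophages, 0.506 for endothelial and mural cells, 0.874 for keratinocytes, 0.408 for osteoblasts and osteoclasts, 0.284 for adipocytes and muscle and 0.409 for synovial fibroblasts. With aging SNL replicate 1 left out camera called proteases (adjusted p = 0.00626), protease inhibitors (0.00565), dedifferentiation genes (0.00683) and markers of macrophages (0.0163) and of adipocytes and muscle (0.0339) higher. In the fit without replicate 2 it called proteases lower (0.039) and interferon-stimulated genes higher (0.0378). With an estimated correlation 0 lists were called in these 2 fits (lowest adjusted p = 0.723 and 0.542). Without spesolimab replicate 1 camera called interferon-stimulated genes higher (0.00198) and oxidative phosphorylation lower (0.042). Without spesolimab replicate 2 it called immediate early genes lower (0.0355) and markers of macrophages (0.00567) and of adipocytes and muscle (0.000172) higher. An estimated correlation was not run without a spesolimab library. In the 6 libraries camera with it gave the lists called in those fits an adjusted p of 0.723 to 0.926.

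Across all genes, edgeR called 0 of 13399 genes in spesolimab against aging SNL, with a lowest adjusted p of 0.956, and 392 genes had an unadjusted p under 0.05 where 670 are expected by chance. The groups did not overlap in 26.9% of genes, where chance gives 33.3%. Limma on TPM called 0, and DESeq2 called 3, which were named after their values were seen: Plau, Galnt14, at 2.36 and 2.89 CPM in aging SNL and 8.53 and 6.12 CPM with spesolimab, and Gm44504, at 1.24 and 1.33 CPM against 6.02 and 4.18 CPM, each with a DESeq2 adjusted p = 0.0219. Without aging SNL replicate 1 edgeR called 0 genes, a count that changes if the replicates are taken as paired, and without replicate 2 it called 2810, 1316 higher and 1494 lower. The largest rises without replicate 2 were in Ngfr, Magel2, Matn3 and Itih5l-ps and the largest falls in Nos2, Cxcl2, Vnn1 and Vnn3. Vnn1, a pantetheinase, was at 469 and 31.3 CPM in aging SNL and at 11.4 and 14.8 CPM with spesolimab, against 15.7 and 26.1 CPM in control.

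**Figure D2:**
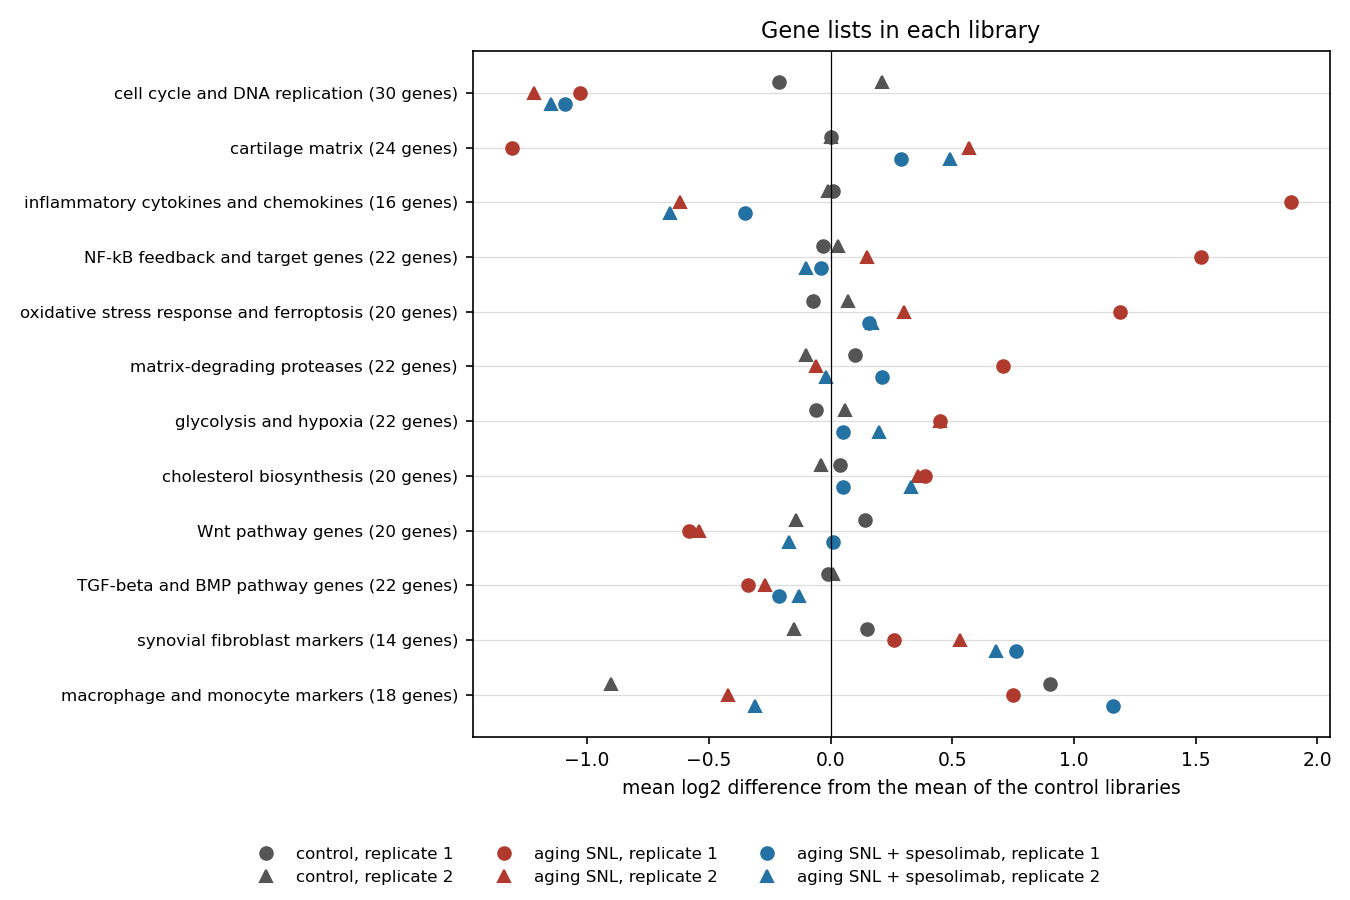
Mean log2 difference from the control mean over the measured members of 12 gene lists, 1 point per library. The glycolysis and hypoxia list is at 0.45 and 0.45 in the aging SNL libraries and at 0.05 and 0.20 with spesolimab, while the cartilage matrix list is at -1.31 in aging SNL replicate 1 and at 0.57 in replicate 2.

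The design also asks whether changes under aging SNL were reversed by spesolimab. Lists called in opposite directions in the 2 comparisons were 6: NF-kB targets, oxidative stress, glycolysis and hypoxia, cholesterol biosynthesis, TGF-beta and BMP, and Wnt. Because both comparisons share the aging SNL libraries with opposite sign, chance alone favours opposite directions. With a different aging SNL library in each comparison, so that no library was shared, 4 of the lists were called in opposite directions when replicate 1 was used in the first and replicate 2 in the second. These were NF-kB targets (camera adjusted p = 3.61e-09 and 0.00499), glycolysis and hypoxia (0.00481 and 4.28e-09), cholesterol biosynthesis (0.00481 and 0.00164) and Wnt (0.0156 and 0.00164). With the libraries used the other way round only the glycolysis and hypoxia list was (5.56e-08 and 0.0388). That form of the test for lists was chosen after the data were seen, and none of the lists was called with an estimated correlation in 6 libraries or with 1 aging SNL replicate left out. The lowest adjusted p was 0.594 in the first comparison and 0.723 in the second without replicate 1, and 0.631 and 0.542 without replicate 2.

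For single genes edgeR called 0 in opposite directions and DESeq2 called 3, Plau, Galnt14 and Gm44504. The log2 fold changes of all genes in the 2 comparisons had a covariance of -0.15, against -0.0693 in simulated unchanged libraries, which ranged from -0.0742 to -0.0646, and a correlation across genes of -0.665 against -0.5. On means of log2 CPM, where the observed covariance was -0.122, the spread of the 2 aging SNL libraries alone gave an expected covariance of -0.156. With a different aging SNL library in each comparison the covariance was 0.0167 or 0.0514 on that scale, so opposite directions over all genes were not seen beyond the shared libraries. Replicate differences correlated by 0.246 to 0.419 between groups. An effect shared by replicate number would raise both values, so a weak reversal is not excluded.

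**Figure D3:**
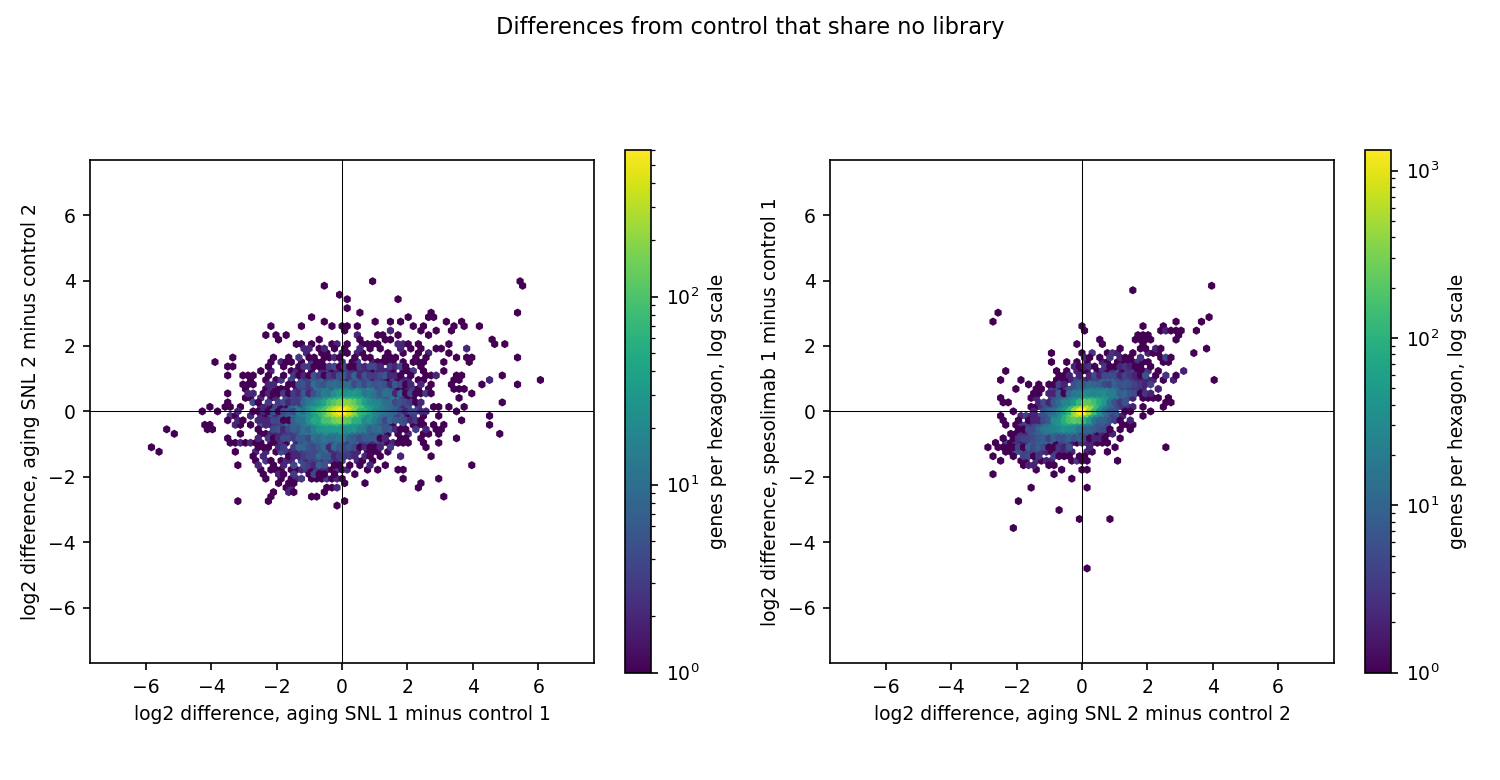
Differences in log2 CPM over 13399 genes between pairs of libraries that have no library in common; each hexagon is shaded by its number of genes. Left, aging SNL replicate 1 minus control 1 against aging SNL replicate 2 minus control 2, with a correlation across genes of 0.256 (0.0672 with the controls exchanged); right, aging SNL replicate 2 minus control 2 against spesolimab replicate 1 minus control 1, with 0.611 (0.183 with the controls exchanged).

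Cells with spesolimab were compared with control cells to ask how far they remained from control. The cell cycle list fell with 30 of 30 members lower, and Mki67 was at 84.2 and 114 CPM in control and at 32.9 and 33.7 CPM with spesolimab. Serpina3n was at 619 and 591 CPM in control and at 3200 and 3900 CPM with spesolimab, 2.55 ± 0.14 higher on the log2 scale in the 4 libraries compared (edgeR adjusted p = 0.00235). Synovial fibroblast markers rose with 12 of 14 higher, and Clec3b, which encodes tetranectin, was at 10.9 and 13.7 CPM in control and at 30.1 and 43.2 CPM with spesolimab. Cholesterol biosynthesis genes and chondrocyte transcription factors also rose as groups. With an estimated correlation all 4 list calls were lost (adjusted p = 0.472 for the cell cycle and synovial lists, 0.995 for cholesterol and 0.94 for transcription factors), and the last 2 also without spesolimab replicate 2 (camera adjusted p = 0.282 and 0.146). Fry called 0 lists in this comparison in the 6 libraries.

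The cell cycle list had a camera adjusted p = 4.92e-34, adjusted p = 0.472 with an estimated correlation, and 24 members lower when adjusted over the list alone, of which none passed over all genes in the 6 libraries and 18 members did in the 4. Synovial fibroblast markers had a camera adjusted p = 0.000644, and adjusted p = 0.472 with an estimated correlation. In the 4 libraries edgeR called 5 of them higher, among them Cd55, at 27.1 and 20.9 CPM in control and 47.7 and 70.9 CPM with spesolimab, and Ly6a, at 174 and 235 CPM against 344 and 411 CPM. Prg4, another of the 5, was at 162 and 144 CPM against 261 and 228 CPM. The 19 of 20 cholesterol genes that were higher gave a camera adjusted p = 0.000359, and adjusted p = 0.995 with an estimated correlation. For chondrocyte transcription factors, with 14 of 18 higher, camera gave an adjusted p = 0.0266, and adjusted p = 0.94 with an estimated correlation, with Foxo3 at 86 and 84.7 CPM in control and 131 and 134 CPM with spesolimab.

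In the fit of the 4 libraries, camera called 11 lists. The cytokine list fell (adjusted p = 0.000348; adjusted p = 0.628 with an estimated correlation), with 4 members called lower: Csf1, at 688 and 617 CPM in control and 432 and 381 CPM with spesolimab, Cxcl1, at 53.4 and 76.8 CPM against 29.2 and 33.3 CPM, Il6, at 7.6 and 10.1 CPM against 3.04 and 1.82 CPM, and Ccl2, at 155 and 125 CPM against 67.7 and 48.1 CPM. The cartilage matrix list rose (adjusted p = 0.000138; adjusted p = 0.628 with an estimated correlation), with 4 members called higher, among them Ucma, at 592 and 450 CPM against 986 and 968 CPM, and Epyc, at 204 and 210 CPM against 273 and 320 CPM. Neither list was called in the 6 libraries, where camera gave an adjusted p of 0.16 for cytokines and 0.127 for cartilage matrix. Saa3, at 845 and 545 CPM in control and 1730 and 1710 CPM with spesolimab, and Lcn2, at 1230 and 995 CPM against 2280 and 2720 CPM, were called higher in the 4 libraries, although their NF-kB list fell there (adjusted p = 0.0463; adjusted p = 0.803 with an estimated correlation). The other lists called in the 4 libraries were complement, up (adjusted p = 0.0425; adjusted p = 0.901 with an estimated correlation), glycolysis and hypoxia, up (adjusted p = 0.0425; adjusted p = 0.887 with an estimated correlation), TGF-beta and BMP, down (adjusted p = 0.0463; adjusted p = 0.628 with an estimated correlation), and endothelial and mural markers, up (adjusted p = 0.0425; adjusted p = 0.628 with an estimated correlation). The complement list stood at 0.68 and -0.07 with spesolimab, beside macrophage markers at 1.16 and -0.31.

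Of the lists called in neither fit of this comparison, camera in the 6 libraries gave an adjusted p of 0.228 for IL-36 and IL-1 family genes, 0.78 for the adaptors and kinases, 0.772 for proteases, 0.141 for protease inhibitors, 0.985 for hypertrophy and mineralization, 0.545 for senescence, 0.829 for interferon-stimulated genes, 0.779 for dedifferentiation and 0.78 for oxidative stress. It was 0.829 for oxidative phosphorylation, 0.985 for the unfolded protein response, 0.953 for heat shock, 0.36 for immediate early genes, 0.36 for Wnt and 0.985 for ribosomal proteins. Among markers of other cells it was 0.16 for macrophages, 0.772 for keratinocytes, 0.858 for osteoblasts and osteoclasts and 0.127 for adipocytes and muscle. Of these, protease inhibitors and markers of macrophages and of adipocytes and muscle were called higher when control replicate 1 was left out (adjusted p = 0.0167, 1.12e-06 and 6.42e-05) or spesolimab replicate 2 (0.00994, 2.71e-05 and 9.29e-06). An estimated correlation was not run in those fits. In the 6 libraries camera with it gave each of these lists an adjusted p of 0.995. On average each list was higher in replicate 1 than in replicate 2 of every group. Read for changes in either direction, fry in the 6 libraries called protease inhibitors (adjusted p = 0.00119) and dedifferentiation genes (0.0403).

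Across all genes, edgeR called 0 of 13399 genes in spesolimab against control in the 6 libraries, with a lowest adjusted p of 0.147 and 827 genes at an unadjusted p under 0.05 where 670 are expected by chance, and limma on TPM called 0. DESeq2 called 160, 66 higher and 94 lower. In the 4 libraries compared, edgeR called 382 genes, 200 higher and 182 lower, against 2081 with the replicate number as a block. The largest rises without the block were in Serpina3m, by 3.89 ± 0.10 (edgeR adjusted p = 5.35e-05), Aox3, an aldehyde oxidase, by 3.13 ± 0.18, Zbtb16, a zinc finger transcription factor, by 2.59 ± 0.19, and Serpina3n. The largest falls were in Pclaf, by 2.05 ± 0.15 on the log2 scale, Kif4, a mitotic kinesin, by 1.99 ± 0.22, Bub1, by 1.91 ± 0.24, and Il6, by 1.86 ± 0.28.

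Genes called in aging SNL replicate 2 against control were also called in spesolimab against control more often than lists drawn independently would be. Of 247 and 200 genes called higher 145 were in both, where 3.72 are expected, and of 220 and 182 called lower 131 were in both, where 3.01 are expected, with 0 in opposite directions. These comparisons share the control libraries. In simulations of unchanged libraries against the same controls 0.4 genes were called in both on average and at most 2, and the covariance of log2 fold changes was 0.032, against 0.175 observed, with a correlation across genes of 0.384 against 0.676. With 2 control libraries they could not be split in a way that keeps 2 on each side, and part of the excess may come from the shared controls. Aging SNL replicate 1 went with the spesolimab libraries in part too. With no library in common their differences from control correlated by 0.275 and 0.29 across genes. Those of the 2 aging SNL replicates correlated by 0.256, or by 0.0672 with the controls exchanged.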

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

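The fits of 4 or 5 libraries with a replicate block and the list tests in 4 libraries were chosen after the results were seen, as was the choice to follow singly only the lists called in at least 1 setting; changes of sign in other lists are not given. The numbers of genes changed rested on the 2 aging SNL libraries and on the tool. In 6 libraries edgeR called 0 genes in each comparison with TMM, DESeq2 size factors, the upper quartile, no filter on low counts, a 2-fold minimum or the replicate block, and limma called 0 on TPM with either pseudocount. The replicates share only a number, and no label says that they share an animal, batch or day, so they were not paired. Differences between replicates correlated across genes by 0.246 to 0.419 between groups. With the replicate block 9 lists were called in spesolimab against control in place of 4, 8 in aging SNL against control in place of 7, and 9 in spesolimab against aging SNL in place of 10, where the adaptor list was lost (camera adjusted p = 0.0511). The block also turned the protease inhibitors in spesolimab against aging SNL (adjusted p = 0.947). In aging SNL against control it turned Matn3 (log2 fold change -0.18) and Acan (-0.28). Added to smaller sets, the replicate block gave 2081 genes in spesolimab against control in 4 libraries. In the 5 libraries without aging SNL replicate 1 it gave 2067 for aging SNL against control, 195 for spesolimab against aging SNL and 2204 for spesolimab against control. Few degrees of freedom remain there, and the cause was not tested.

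For aging SNL against control a filter of 10 CPM gave 5 genes, where fewer genes were tested, and DESeq2 gave 445. DESeq2 gave 3 for spesolimab against aging SNL, 3 for genes changed in opposite directions and 160 for spesolimab against control, where the 4 libraries alone gave 382 in edgeR. The cause was not tested. In simulated data DESeq2 made more false calls per draw than edgeR in the 6 libraries, tested for aging SNL against control (55.3 against 6), and fewer without aging SNL replicate 1 (11.7 against 25.3) and in the 4 libraries (17 against 26.3). With 1 library left out the numbers of genes went from 0 to 3525 for aging SNL against control (467 without aging SNL replicate 1, 3525 without replicate 2), from 0 to 2810 for spesolimab against aging SNL, from 0 to 385 for spesolimab against control and from 0 to 2304 for opposite directions. The numbers above 0 all came without an aging SNL replicate, in fits where the lone library is assumed to vary like the other groups. On log2 CPM values the covariance of the 2 fold changes, -0.122 with shared libraries, was 0.0167 and 0.0514 without.

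The numbers of lists called rested on the correlation between genes that camera assumes. With an estimated correlation they were 0, 0 and 0 in the 3 comparisons, and with fry 1, 1 and 0. With DESeq2 size factors they stayed at 7, 10 and 4. The 4 libraries of spesolimab against control gave 11. With 1 library left out they went from 7 to 13 for aging SNL against control, from 8 to 11 for spesolimab against aging SNL and from 5 to 11 for spesolimab against control. There were 53 entries, each a list in a comparison that was called in at least 1 setting. Of these 21 lost their call with an estimated correlation, which were all those called by camera in the main fit. With fry 19 lost it. Fry turned the proteases in both comparisons with aging SNL (adjusted p = 0.987 and 0.997) and the protease inhibitors in spesolimab against aging SNL (0.997), and DESeq2 size factors turned the proteases there (0.999), lists far from the threshold.

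Leaving out 1 library turned the direction of lists as follows, with the range of camera adjusted p over the 6 fits. In aging SNL against control these were cytokines (8.76e-07 to 0.36), cartilage matrix (9.08e-06 to 0.467), proteases (0.0156 to 0.911), protease inhibitors (0.0348 to 0.71) and interferon genes (0.0406 to 0.936), each without aging SNL replicate 1, and chondrocyte transcription factors (0.00858 to 0.561), without replicate 2. Complement (0.0147 to 0.998), macrophage (0.00109 to 0.655) and adipocyte and muscle markers (0.0177 to 0.925) turned without control replicate 2, the last 2 also without aging SNL replicate 1. In spesolimab against aging SNL, cytokines (3.21e-09 to 0.352) and cartilage matrix (3.21e-09 to 0.052) turned without aging SNL replicate 1. Proteases (0.00626 to 0.869) and interferon genes (0.00198 to 0.398) did so without that library and without spesolimab replicate 2. Protease inhibitors (0.00565 to 0.869) and macrophage markers (0.00567 to 0.481) turned without aging SNL replicate 2 and without spesolimab replicate 1, dedifferentiation genes (0.00683 to 0.848) without the first of these, and adipocyte and muscle markers (0.000172 to 0.848) without the second. In spesolimab against control, complement (0.000282 to 0.988), macrophage (1.12e-06 to 0.702) and adipocyte and muscle markers (9.29e-06 to 0.988) turned without spesolimab replicate 1, the last 2 also without control replicate 2.

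Among 112 fold changes of named genes none turned with DESeq2, either scaling, either filter or without a control library or spesolimab replicate 1. The filter of 10 CPM left some of them untested, with 94 unchanged and 2 that gained a call. DESeq2 called 44 of the 112. With aging SNL replicate 1 left out edgeR called 46 and 11 turned, and with replicate 2 left out it called 90 and 4 turned; many of these genes were named from those fits. In aging SNL against control log2 fold changes ranged from -2.93 to 2.93 for Magel2, from -2.1 to 0.56 for Gask1b, from -5.07 to 0.36 for Ostn, from -4.11 to 1.66 for Matn3, from -3.97 to 0.07 for Cyb5r2, from -0.26 to 0.93 for Il1rap, from -1.1 to 0.44 for Sox9, from -2.3 to 1.27 for Acan and from -2.51 to 0.06 for Col2a1. In spesolimab against aging SNL they ranged from -0.75 to 5.1 for Magel2, from -0.72 to 4.75 for Itih5l-ps, from -1.76 to 0.09 for Il1rl2, from -0.95 to 0.25 for Il1rap, from -0.19 to 1.35 for Sox9, from -0.62 to 2.95 for Acan and from -0.98 to 4.79 for Matn3, which stood at 0.00 in 6 libraries and is not counted among those that turned. The extremes came without 1 or the other aging SNL replicate, and Magel2, Itih5l-ps and Acan also turned in spesolimab against aging SNL without spesolimab replicate 2. Depth set the limit only for genes of low expression, with a counting error of 11% at 5 CPM.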

Other observations

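Of the tests below, those of macrophages, of a stronger form of the response, of the shared controls and, for a swap, the correlation of the controls were chosen only after the result was seen. Errors given below for lists are standard errors of the mean across genes and do not measure the spread between libraries. On average, markers of macrophages, of adipocytes and muscle, and of osteoblasts and osteoclasts were higher in replicate 1 than in replicate 2 of each group. The macrophage list stood 0.90 and -0.90 from the control mean in control, 0.75 and -0.42 in aging SNL and 1.16 and -0.31 with spesolimab on the log2 scale. Adipocyte and muscle markers stood at 0.61 and -0.61, 0.66 and -0.16, and 1.19 and -0.22. Osteoblast and osteoclast markers stood at 0.24 and -0.24, 0.36 and -0.43, and 0.40 and -0.41. Lyz2 was at 70.6 and 13.6 CPM in control, 78.3 and 22.8 in aging SNL and 97.4 and 19.8 with spesolimab, and Cd68 at 7.54 and 2.41, 17.4 and 3.25, and 9.4 and 2.77 CPM. Adipoq was an exception in aging SNL, at 6.65 and 13.6 CPM, against 19.4 and 7.23 in control and 32.4 and 15.1 with spesolimab. Camp, the 1 gene tested of the neutrophil and lymphocyte list, was at 1.14 and 0.729 CPM in control, 3.23 and 4.64 in aging SNL and 0.467 and 1.94 with spesolimab. In aging SNL against control it differed by 2.06 ± 0.67 on the log2 scale (edgeR adjusted p = 0.34). Fkbp5, which glucocorticoids induce, was at 11.9 and 12.4 CPM in control. It was at 74.8 and 61 CPM in aging SNL and at 46.4 and 58 CPM with spesolimab. Zbtb16 was at 7.72 and 5.16 CPM in control. It was at 55 and 39.1 CPM in aging SNL and at 35.3 and 42.4 CPM with spesolimab.

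Aging SNL replicate 1 stood apart from the other 5 libraries in inflammatory and cartilage genes. More macrophages in that culture would raise their markers, which were on average lower than in spesolimab replicate 1 (-0.41 ± 0.22 over 18 genes) and not higher than in control replicate 1 (-0.15 ± 0.24), and the trend on transcript length spanned 0.204 on the log2 scale, so that its removal left 97.6% of the 1857 genes over 2-fold apart between the aging SNL replicates. A swap with a control library would need a control out of place, but the controls correlated by 0.9895 with each other and by at most 0.9779 with an aging SNL library. Of 276 genes called alike in aging SNL replicate 2 and in spesolimab against control, 76.4% went that way in aging SNL replicate 1. The exact 95% interval, 71 to 81.3, treats genes as independent and holds the bound of 75% set beforehand. The genes were picked as differing from the same controls, which favours that direction in any library. The share therefore cannot decide on a swap. A stronger form of the response of replicate 2 is argued against for the cartilage matrix list, which was higher than control in replicate 2 (0.57 ± 0.16) and lower in replicate 1 (-1.31 ± 0.28). The closest of all 15 pairs of libraries were aging SNL replicate 2 and spesolimab replicate 2 (0.9926), so a single wrong label of either aging SNL library, a swap with a sample outside the series, an additional stimulus in that culture and a real difference between cultures or animals under the condition may each apply and were not tested.

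Genes changed alike against control in aging SNL replicate 2 and in the spesolimab libraries were more than the shared controls alone would give, since the differences correlated by 0.183 to 0.653 across genes in the 4 pairings with no library in common, lowest with replicate numbers crossed in opposite directions. Higher glucocorticoid activity in both aging SNL groups may be part of this: Fkbp5 and Zbtb16 prompted a list whose 13 members not yet seen had a median log2 fold change of 0.72 (SE 0.17) in spesolimab against control in 4 libraries (camera p = 4.19e-15 with the preset correlation; p = 0.0142 with an estimated correlation; fry p = 0.000429), 12 of 13 higher and 8 called higher, among them Tsc22d3, Per1, Klf9 and Pdk4. Lower activity of serum response factor may be another part, as 16 targets not yet seen had a median of -0.5 (SE 0.11) there (camera p = 4.05e-10 with the preset correlation; p = 0.098 with an estimated correlation; fry p = 0.0344), with 1 higher and Myl9, Flna, Tpm2 and Fhl2 called lower. The SEs given with these medians are those of the mean across genes. In aging SNL replicate 2 the medians were 0.41 and -0.78. Both remain hypotheses: the lists were written after the first fit, many of their genes respond to other signals, and a difference in medium or additives between control and the other groups is confounded with the condition.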
